A study of Mus musculus with 9 samples.

How the data were processed

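Total RNA from the proximal colon of 9 mice was measured on an Affymetrix mouse array with 22690 probe sets. Per the labels, mice carrying the cSHMT mutation had been backcrossed to C57Bl/6 for 10 generations and were weaned at 3 weeks of age onto a diet without folate and choline. The labels give the time on that diet as 6 weeks in the sample characteristics and as 5 weeks in the growth protocol, and the age as 9 weeks. They do not describe how Shmt1 was altered or whether the mutant allele is null. About 50 ng of total RNA per colon was amplified with the NuGEN Ovation kit and labelled with biotin, per the labels. The kit is known to prime in part from the poly(A) tail, so shortened RNA reads higher at the 3' end than at the 5' end of a transcript.

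The values deposited by the authors are intensities, 1 signal per probe set and array on a linear scale. The submitters' processing notes name GCOS, the Affymetrix operating software, and its version and scaling are not given in the sources used here. The trimmed mean of the signals lay between 500.1 and 500.2 in every array, while the medians of log2 signal spread over 0.294. Because a limit of 0.2 on that spread had been set, the values were quantile normalized after adding 16 and taking log2, and the values as deposited became an alternative. The added 16 makes fold changes of dim probe sets smaller than they are. Mean signals and SDs in the text are the deposited linear values; fold changes come from the normalized log2 scale.

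The 64 control probe sets were left out. Probe sets whose mean over all 9 arrays lay under the 40th percentile were left out before the adjustment, which left 13576 of 22626; the linear signal at that limit was 75.5. The highest signal of the Bacillus control probe sets that should find no target was 10.9. Gene names came from the platform's annotation, which can be old. Of all probe sets 20380 have 1 gene symbol, 691 several and 1555 none here, and of those tested 12489, 448 and 639. Probe sets with several symbols or none were counted and not named. A gene table of assembly GRCm38.p6 was used only for synonyms, for the chromosome and for which genes neighbour each other, since the array names no genome build.

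Each probe set was tested with limma (lmFit and eBayes with a trend, version 3.58.1, R 4.3.3), all 9 arrays in 1 fit with no covariate. Calls used a Benjamini-Hochberg adjusted p of 0.05 in each of 3 comparisons: mutant against wild-type and heterozygous against wild-type, as the design text states, and mutant against heterozygous. Before the data were examined, 28 gene lists with 490 genes were fixed, 13 of pathways and 15 of cell type markers; 428 of the genes are named on the array, 2 of them through a synonym. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, on the probe set with the highest mean of each of 8202 genes, with Benjamini-Hochberg adjustment over the 23 lists that had at least 5 measured members. Camera with an estimated correlation and fry were alternatives. Members of a list were also adjusted over the list alone.

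The genes named in the text follow a rule fixed before the data were examined. It takes Shmt1, each list member that passed, up to 4 members per list with the smallest p, and per comparison and direction 10 genes whose 3 values in one genotype do not overlap the 3 in the other. Where fewer than 10 passed, those with the smallest unadjusted p fill the places, and they are said not to have passed. Neighbours of Shmt1 and single immunoglobulin probe sets in the closing part were chosen after their values were seen.

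The test was tried on simulated data with known changes. At once, 50 probe sets each were changed 1.5-, 2-, 4- and 8-fold, with noise drawn independently for each probe set. At the spread of these arrays, it recovered 44% of probe sets changed 1.5-fold and 94% of those changed 2-fold in mutant against wild-type, 42% and 92% in heterozygous against wild-type, and 44% and 92% in mutant against heterozygous. Among the unchanged of the 13576 probe sets it called 6, 10 and 9. So many true changes loosen the adjusted threshold. Where few probe sets change, as the few calls in the real arrays leave possible, recovery would be lower. For the correlation of the 2 genotypes' fold changes, 3 groups without any change were simulated 1000 times from the spread of arrays within genotypes. The same simulated group served as wild-type in both comparisons.

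The labels give no sex. Eif2s3y, on the Y chromosome, was high in all 9 arrays and Xist low, so no split by sex was made. The list of 3 measured sex-linked genes had median log2 fold changes of -0.09, 0.24 and -0.32 in the 3 comparisons and was not tested. Python 3.11.15 with matplotlib 3.10.9 drew the figures. Alternatives were the values as deposited, centring on the median, other filters and pseudocounts, eBayes without the trend or with robust fitting, only the 2 genotypes compared, the replicate number as a block, array weights, other thresholds, the mean of all probe sets of a gene, and leaving out each array. Leaving out the 3 arrays numbered 1 and taking the beta-actin 3'/5' ratio as a covariate were chosen after seeing the data.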

Results

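Gene expression was measured in the proximal colon of 9 mice that had been weaned onto a diet lacking folate and choline. The mice differed in their genotype at Shmt1, the gene of cytosolic serine hydroxymethyltransferase (cSHMT), the enzyme that transfers a carbon unit between serine and tetrahydrofolate in the cytoplasm. There were 3 wild-type, 3 heterozygous and 3 mutant mice, each on its own Affymetrix array, so the number of arrays limits the precision of every value below. The labels call them biological replicates. They give the age as 9 weeks, and they give the time on the diet as 6 weeks in one field and 5 weeks in another. Each array held 22690 probe sets, of which 13576 were bright enough to be tested. The arrays were alike over all probe sets, with correlations of log2 signal between 0.9657 and 0.9868 over the 36 pairs. Per-array medians lay between 129.4 and 162.1 signal units. The array numbered 1 in each genotype had the highest ratio of 3' to 5' beta-actin signal, 5.02, 4.46 and 4.84 in wild-type, heterozygous and mutant, against 2.52 to 3.75 in the other 6 arrays. This ratio reads how far the labelled RNA was shortened from its 5' end.

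Shmt1 itself was read by 4 probe sets, and on each the mean signal was highest in wild-type and lowest in mutant colons. On the Shmt1 probe set that differed most the signal was 594.7 ± 43.2 (SD, n = 3) in wild-type, 303.1 ± 31.6 in heterozygous and 116.7 ± 3.46 in mutant colons, that is, 51% and 19.6% of the wild-type mean. The 3 genotypes did not overlap on this probe set. On each of the others the mutant arrays lay below all other arrays, but a heterozygous array reached the wild-type values. The leading Shmt1 probe set, the one with the highest mean log2 signal by a rule fixed before the data were examined, read 493.5 ± 33.4 in wild-type, 417.9 ± 67.9 in heterozygous and 258.4 ± 25.3 in mutant colons. Its log2 fold change was -0.89 (SE 0.176) in mutant against wild-type, with an adjusted p of 0.596 over all probe sets tested and 0.00456 adjusted over the list alone of folate genes. In heterozygous against wild-type it was -0.25 (SE 0.176, adjusted p = 0.728). Another probe set of Shmt1 read 55.5% of wild-type in mutant and 76.9% in heterozygous colons (adjusted p = 0.309 and 0.584). The dimmest, too low to be tested, read 24.1 in wild-type, 22.8 in heterozygous and 5.9 in mutant colons. Where each probe set lies relative to the altered part of the gene was not analysed here.

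**Figure D1:**
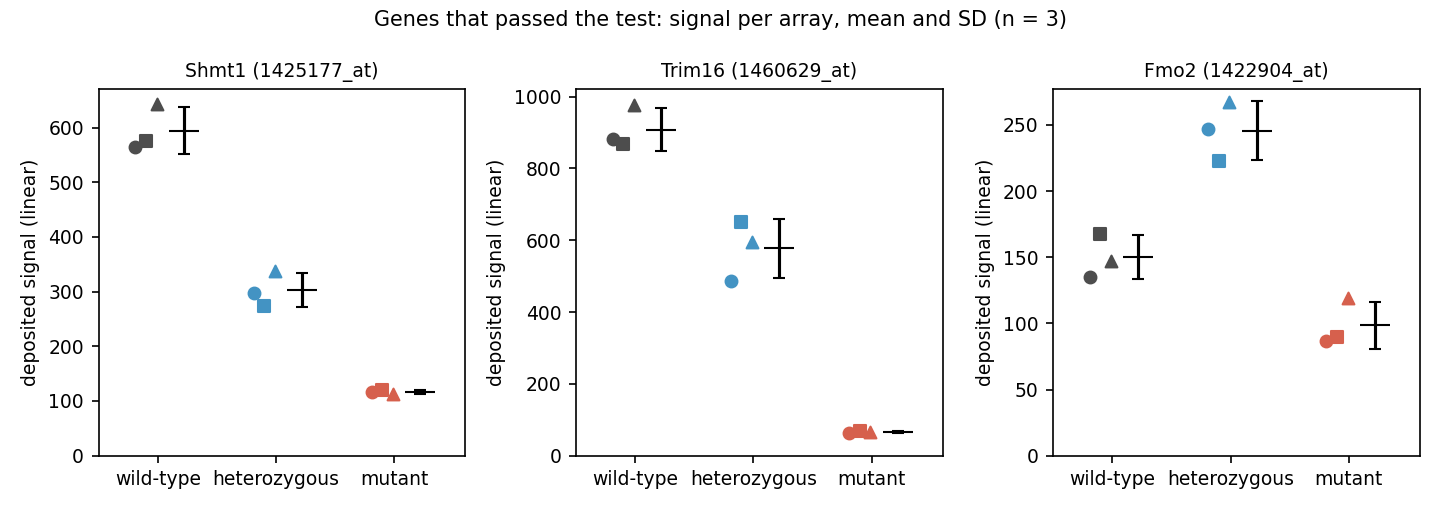
Deposited signal (linear scale) of Shmt1, Trim16 and Fmo2 in each array, by genotype, with circles, squares and triangles for the arrays numbered 1, 2 and 3 and a black bar for the mean and SD of 3 arrays. Shmt1 and Trim16 were highest in wild-type and lowest in mutant colons, while Fmo2 was highest in heterozygous colons at 245.6.

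Mutant against wild-type asked how the mutant genotype at Shmt1 changes expression in the colon when folate and choline are lacking. Apart from Shmt1 itself, the gene that changed most was Trim16, which encodes a tripartite motif protein. On one of its 2 tested probe sets the signal fell from 907.8 ± 59 to 65.93 ± 3.83 (SD, n = 3), an 11.1-fold decrease (log2 fold change -3.48, SE 0.125, adjusted p = 1.59e-07), with 576.9 ± 82.2 in heterozygous colons. On the other Trim16 probe set the log2 fold change was -0.79, which did not pass (unadjusted p = 0.0065). Shmt1, on the probe set that differed most, fell 4.56-fold (log2 fold change -2.19, SE 0.134, adjusted p = 2.64e-05). These were 2 of the 3 probe sets that passed an adjusted p of 0.05, all of them lower in mutant colons; the other probe set carries several gene symbols and is not named. In limma's test, 521 probe sets had an unadjusted p under 0.05, where 679 would be expected by chance. The count of 3 rose to 9 without the 3 arrays numbered 1, all lower, and to 9 with array weights, of which 3 were higher and 6 lower.

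**Figure D2:**
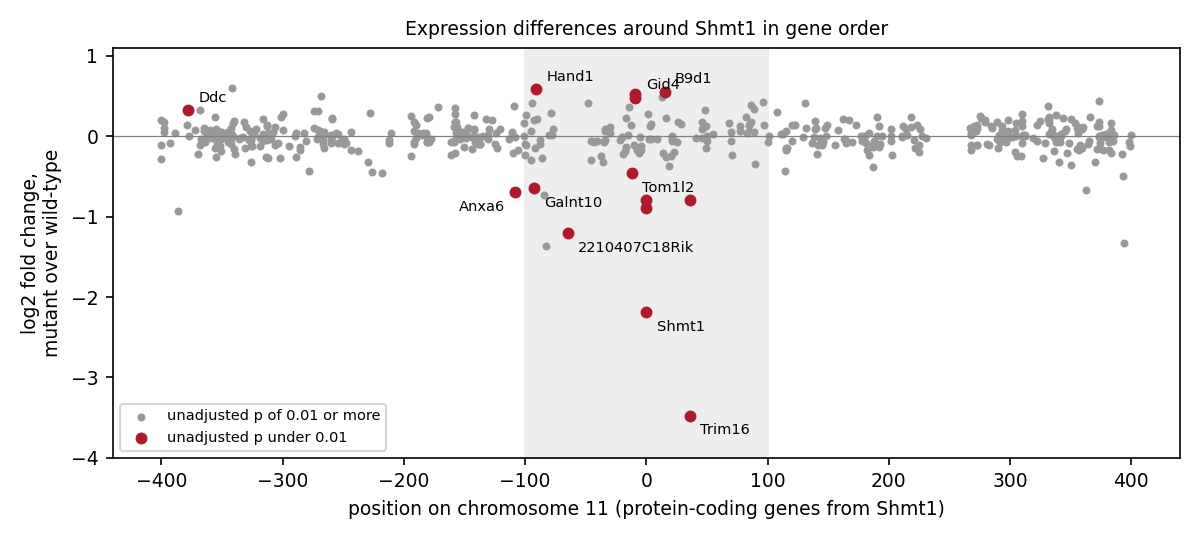
Log2 fold change of mutant over wild-type for tested probe sets within 400 protein-coding genes of Shmt1 on chromosome 11, in gene order, with red for an unadjusted p under 0.01 and grey shading for 100 genes on each side. Trim16, 36 genes from Shmt1, had the largest change.

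The genes next in rank did not pass, and their values are given as measured. Among those lower in mutant colons, 2210407C18Rik read 4706 ± 216 in wild-type and 2021 ± 326 in mutant colons (log2 fold change -1.21, adjusted p = 0.0522); it passed in 7 of 13 alternatives and in 2 of 9 fits without an array. Psmd3, a subunit of the proteasome, read 1089 ± 25.1 and 560.4 ± 115 (adjusted p = 0.171), and its heterozygous value of 624.9 ± 134 lay close to the mutant one. The log2 fold changes of Sla, a Src-like adaptor, Galnt10, a glycosyltransferase, Ighm, the immunoglobulin mu chain, and Nrg4, a ligand of the EGF family, were -0.76, -0.65, -0.84 and -1.02. Those of Bcl6, a transcriptional repressor, and Fmo2, a flavin-containing monooxygenase, were -0.48 and -0.52. Their adjusted p-values lay between 0.742 and 0.998. Another tested probe set of Galnt10 went the other way, with a log2 fold change of 0.20. On the higher side, Hk1, a hexokinase, read 1021 ± 18.4 in wild-type and 1459 ± 67.7 in mutant colons (log2 fold change 0.50, adjusted p = 0.587). Gid4, a subunit of a ubiquitin ligase, read 707.2 ± 23.5 and 995.4 ± 16.1 (log2 fold change 0.48, adjusted p = 0.742). Cenpf and Nek2, which act in mitosis, had log2 fold changes of 0.73 and 0.57. The rest of the 10 genes with the smallest p on this side were Poldip3 (0.66), Svil (0.69), Ino80b (0.63), Hnrnpr (0.47), Pa2g4 (0.52) and B9d1 (0.55), none of which passed.

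Of the 23 gene lists tested, 5 were shifted in mutant against wild-type colons, 4 down and 1 up. None of the 5 was called with an estimated correlation between genes (adjusted p = 0.682 with an estimated correlation for each; the estimate for the interferon list was 0.86). Genes induced by interferon were lower, 22 of 23 with a median log2 fold change of -0.73 (camera adjusted p = 6.22e-12). Psmb8, a subunit of the immunoproteasome, read 1156 ± 135 in wild-type and 680.5 ± 240 in mutant colons, and Ifit3 read 412 ± 125 and 183.7 ± 96.2. Mx1 and Bst2, both antiviral proteins, had log2 fold changes of -0.70 and -0.65. The 4 T cell markers measured were also lower, with a median log2 fold change of -1.02, but were too few to be tested as a list. Macrophage and myeloid markers were lower in 11 of 11 genes with a median of -0.26 (adjusted p = 0.000157), for example Lyz2 at -0.36 and C1qa at -0.26. Adipocyte markers were lower in 7 of 7 genes with a median of -0.59 (adjusted p = 2.51e-05). Fabp4, the fatty acid carrier of adipocytes, read 4356 ± 742 in wild-type and 2803 ± 863 in mutant colons. Cell cycle genes were higher, 22 of 25 with a median of 0.20 (adjusted p = 5.7e-05). The cell cycle mean per mouse was 8.62, 8.58 and 8.57 in wild-type and 8.95, 8.59 and 8.85 in mutant colons, so mutant 2 lay within the wild-type values. Cdc20, an activator of the anaphase-promoting complex, read 304.8 ± 14.1 and 489.4 ± 69.7, and Ccnb2, a mitotic cyclin, 452.6 ± 14.3 and 623.6 ± 45. Circadian clock genes were lower, 11 of 15 with a median of -0.14 (adjusted p = 0.0426), led by Tef at -0.45 and Per2 at -0.70.

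No member of these 5 lists passed on its own, over all probe sets or adjusted over the list alone. The mean of the interferon list per mouse was 9.72, 9.15 and 9.17 on the log2 scale in wild-type and 9.38, 8.27 and 8.05 in mutant colons, so mutant 1 lay within the wild-type values (exact permutation test, two-sided, p = 0.3, where 0.1 is the smallest possible). The adipocyte mean was 9.72 in mutant 1 and at least 10.64 in the other 8 arrays, and the list was no longer called without the 3 arrays numbered 1 (adjusted p = 0.326). The macrophage list lost its call without wild-type 1 (0.151) or mutant 3 (0.126), and the circadian list did so in 8 of the 9 fits that left out an array (up to 0.154).

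**Figure D3:**
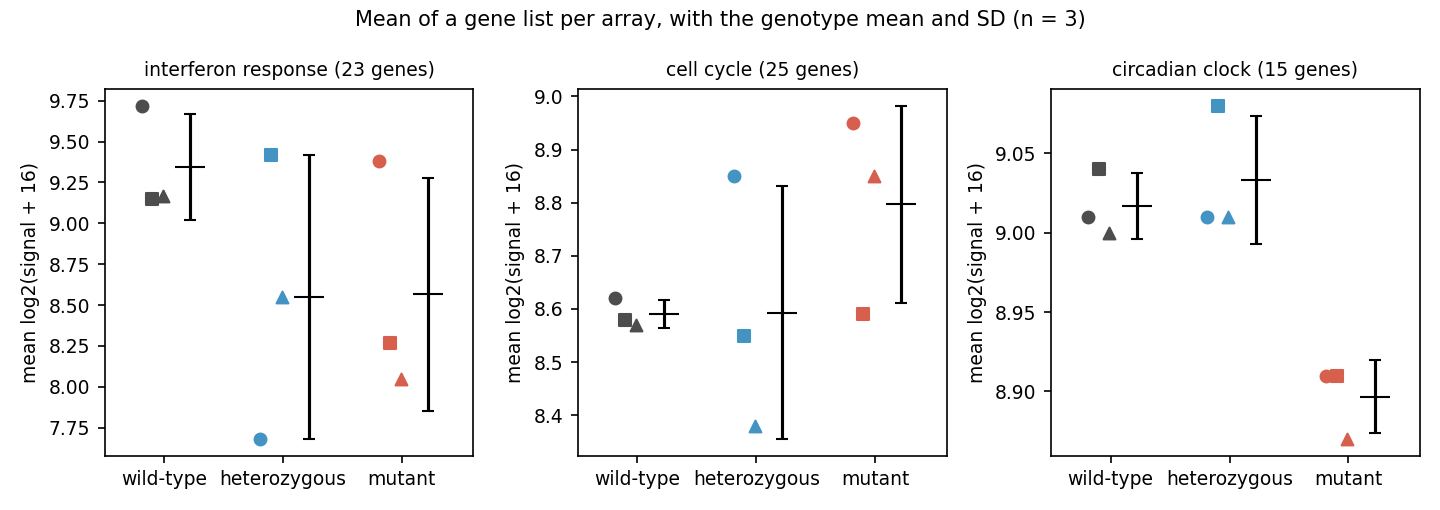
Mean log2(signal + 16) of the genes of 3 lists in each array, by genotype, with circles, squares and triangles for the arrays numbered 1, 2 and 3 and a black bar for the mean and SD of 3 arrays; the vertical axes differ. The interferon mean ranged from 7.68 in heterozygous 1 to 9.72 in wild-type 1, whereas the circadian mean of the mutant arrays lay between 8.87 and 8.91, below every other array.

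The folate pathway showed little besides Shmt1. Of its 13 measured genes 1 fell when adjusted over the list alone, Shmt1, and the other 12 did not pass (list adjusted p = 0.549). Ggh, which trims folate polyglutamates, had a log2 fold change of 0.32 (unadjusted p = 0.0308), Aldh1l1 -0.36 and Gart, an enzyme of purine synthesis, -0.21. None of the 21 genes of nucleotide synthesis, 20 of methionine, choline and methylation, 17 of serine synthesis and the ATF4 response, 18 of the p53 response or 15 of DNA repair passed, also adjusted over the list alone. Their list medians were 0.06, 0.01, -0.01, -0.03 and 0.11 (list adjusted p = 0.198, 0.873, 0.636, 0.47 and 0.181). The largest single values were 0.63 for Aldh18a1, 0.43 for Dck and 0.43 for Xrcc1. Nor did the lists of Wnt pathway and crypt base genes (median -0.01), cholesterol and fatty acid synthesis (0.09), mucosal defence and acute inflammation (-0.02) and oxidative phosphorylation (0.00039) pass.

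None of the lists of markers of the colon's own cell types was called in mutant colons. Medians were -0.00232 for 15 absorptive colonocyte genes, -0.02 for 10 goblet cell genes, -0.02 for 9 enteroendocrine genes, -0.01 for 13 smooth muscle genes, -0.19 for 9 genes of enteric neurons and glia (8 of 9 lower, adjusted p = 0.09), -0.03 for 12 fibroblast and matrix genes and -0.09 for 7 endothelial genes. Small intestine epithelium had a median of -0.04 over 9 genes and was not called. In lists that were not called the median could differ in sign from the mean or the test; for absorptive colonocytes and mucosal defence both were positive, for goblet cells the test and for enteroendocrine cells the mean. Of the 3 B and plasma cell genes measured, Ighm fell on its leading probe set when adjusted over the list alone (log2 fold change -0.84, adjusted p = 0.00377). Not all other Ighm probe sets moved with it. Jchain had a log2 fold change of -0.13. Exocrine pancreas (2 genes, median 0.06) and blood (1 gene, Hbb-b2, 0.12) were near wild-type.

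Heterozygous against wild-type asked the same of the heterozygous genotype. No probe set passed in limma's test, with 1087 at an unadjusted p under 0.05 where 679 would be expected by chance. With array weights, which give less weight to arrays that fit poorly, 134 passed. Shmt1, on the same probe set, had a log2 fold change of -0.94 (SE 0.134, unadjusted p = 2.01e-05, adjusted p = 0.232), and Trim16 -0.65 (adjusted p = 0.323). The other genes with the smallest p among those lower in heterozygous colons did not pass either. Col5a2, a collagen gene, read 1254 ± 92.7 in wild-type, 744.8 ± 115 in heterozygous and 1190 ± 89.6 in mutant colons (log2 fold change -0.76 in heterozygous, adjusted p = 0.323). Col4a1 and Col6a3, also collagen genes, each had a log2 fold change of -0.49. Cnn1, the smooth muscle protein calponin, read 2373 ± 222 in wild-type and 1523 ± 203 in heterozygous colons. Ighm (-1.30), Psmd3 (-0.82), Bag2 (-0.73) and the transporter gene Slco3a1 (-0.68) completed these 10. On the higher side stood Timp3, an inhibitor of metalloproteinases, with 610.2 ± 60 in wild-type and 945.5 ± 27.8 in heterozygous colons (log2 fold change 0.61, adjusted p = 0.323). Nup153, a nucleoporin, had a log2 fold change of 0.63 and Fmo2 one of 0.64. The other 7 were Poldip3 (0.76), Slc35a5 (0.64), Tspan12 (0.53), Pa2g4 (0.70), Adi1 (0.66), Hnrnpr (0.58) and Tgfbi (0.66).

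Of the gene lists, 2 were shifted in heterozygous colons, both down, and neither was called with an estimated correlation (adjusted p = 0.696 with an estimated correlation for each). Interferon genes were lower in 23 of 23, with a median of -0.87 (camera adjusted p = 6.48e-08). Cxcl10, an interferon-induced chemokine, read 131.9 ± 20.8 in wild-type and 69.63 ± 40.3 in heterozygous colons, and Mx1 349.1 ± 46.4 and 199.2 ± 91.3. Smooth muscle genes were lower in 10 of 13, with a median of -0.14 (adjusted p = 0.00555). Of these 13, Cnn1 fell when adjusted over the list alone (-0.65, adjusted p = 0.00414) and 12 did not pass, Des having a log2 fold change of -0.37 and Tagln -0.21. Beside them, the 12 fibroblast and matrix genes had a median of -0.18 (list adjusted p = 0.133). Ighm fell, on its leading probe set and not on all others, when adjusted over the list alone of 3 B and plasma cell genes (-1.30, adjusted p = 0.000103), and the 4 T cell genes had a median of -0.66. The interferon means were 7.68, 9.42 and 8.55 in the 3 heterozygous colons, with heterozygous 2 inside the wild-type range (exact permutation test, two-sided, p = 0.3, smallest possible 0.1), and that list was not called without the 3 arrays numbered 1 (adjusted p = 0.102). The smooth muscle list was not called without wild-type 2 (0.111), wild-type 3 (0.376) or heterozygous 1 (0.0665).

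No other list was called between heterozygous and wild-type colons, and where medians are near 0 the mean or the test could have the other sign. Medians were -0.08 for the folate list, 0.00191 for nucleotide synthesis, 0.02 for methionine, choline and methylation, -0.05 for serine synthesis and the ATF4 response, 0.09 for the p53 response, -0.09 for DNA repair, 0.01 for cell cycle genes and -0.01 for Wnt and crypt base genes. They were -0.15 for cholesterol and fatty acid synthesis, 0.02 for mucosal defence, -0.04 for oxidative phosphorylation and 0.16 for the circadian clock. For absorptive colonocytes, goblet cells, enteroendocrine cells, enteric neurons and glia, endothelium, macrophages, adipocytes and small intestine epithelium they were -0.03, -0.01, 0.07, -0.09, -0.03, -0.04, -0.07 and 0.01. The 2 pancreas genes had a median of -0.25, and Hbb-b2 a log2 fold change of 0.14.

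Mutant against heterozygous, which the design text does not list, tests whether the effects of the 2 genotypes differ. There were 3 probe sets that passed, all lower in mutant colons. Trim16 was 7.07-fold lower (log2 fold change -2.82, SE 0.125, adjusted p = 1.56e-06) and Shmt1, again on the probe set that differed most, 2.37-fold lower (SE 0.134, adjusted p = 0.00939). Fmo2 was 2.24-fold lower (log2 fold change -1.16, SE 0.136, adjusted p = 0.0144), with 150.1 ± 16.5 in wild-type, 245.6 ± 22.2 in heterozygous and 98.53 ± 17.9 in mutant colons. Another tested probe set of Fmo2 did not pass. At an unadjusted p under 0.05 there were 1027 probe sets, against 679 expected by chance. Direction depended on the fit: without heterozygous 3, 7 probe sets passed, 5 of them higher in mutant colons. With the replicate number as a block 8 passed, 1 of them higher. The Shmt1 call was lost without heterozygous 1 (adjusted p = 0.065) or mutant 2 (0.0864), and the Fmo2 call without heterozygous 1, heterozygous 3, mutant 1 or mutant 2 (adjusted p up to 0.144), on the values as deposited and with no filter on dim probe sets. Without the 3 arrays numbered 1, their adjusted p-values were 0.0587 and 0.0957.

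The next genes did not pass. Among those higher in mutant than in heterozygous colons, Fmod, the matrix protein fibromodulin, read 33.07 ± 15.2 in heterozygous and 152.3 ± 47.6 in mutant colons (log2 fold change 1.86, adjusted p = 0.132), with 101.1 ± 24.9 in wild-type. Ahcyl2, a relative of S-adenosylhomocysteine hydrolase, had a log2 fold change of 0.91 (adjusted p = 0.132) and Hao2, a peroxisomal oxidase, one of 0.51. The others on this side were Bag2 (0.91), Ppa1 (0.67), Col5a2 (0.67), Col6a3 (0.54), Ccn3 (0.76), Casq2 (0.63) and Cnn1 (0.63). Among those lower in mutant colons were Tsc22d3 (-0.84) and Klf9 (-0.34), both known to be induced by glucocorticoids, and Lepr, the leptin receptor (-1.03). Sla (-0.90), Rcsd1 (-1.07), Celf2 (-0.52) and Timp3 (-0.56) had adjusted p-values between 0.173 and 0.186.

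Between mutant and heterozygous colons 6 lists were shifted. None of the 6 was called with an estimated correlation, the adjusted p being 0.483 for the circadian list, 0.622 for the cell cycle and macrophage lists and 0.584 for the other 3. The circadian clock list had the most members that passed when adjusted over the list alone. Of its 15 genes, 4 fell when adjusted over the list alone, namely Tef (-0.73), Hlf (-0.86), Per1 (-0.70) and Per2 (-1.02), 1 rose, Arntl (1.05, adjusted p = 0.0306), and 10 did not pass (camera adjusted p = 0.014). Arntl encodes the activator of the clock that is known to peak in antiphase to the Per genes. Cell cycle genes were higher in 24 of 25 (median 0.19, adjusted p = 0.0028), none passing alone. Genes of cholesterol and fatty acid synthesis were higher in 16 of 19 (median 0.24, adjusted p = 0.0028). Of these, Elovl6 rose when adjusted over the list alone (0.43, adjusted p = 0.0462) and 18 did not pass, Lss having a log2 fold change of 0.46 and Mvd 0.76. Smooth muscle genes were higher in 11 of 13 (median 0.13, adjusted p = 0.00613), of which Cnn1 (0.63, adjusted p = 0.00492) and Smtn (0.33, adjusted p = 0.0387) rose when adjusted over the list alone and 11 did not pass. Adipocyte markers were lower in 7 of 7 (median -0.55, adjusted p = 0.0028) and macrophage markers in 9 of 11 (median -0.22, adjusted p = 0.00562), none passing alone.

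Each of the 6 calls between mutant and heterozygous colons was lost in at least 2 of the 9 fits that left out an array: without mutant 3 the circadian, cholesterol and smooth muscle lists had an adjusted p of 0.0735, the cell cycle list 0.136 and the macrophage list 0.234, and without mutant 1 the adipocyte list had 0.301. The cell cycle list also lost its call without heterozygous 3 (0.177) or mutant 1 (0.0703), the cholesterol list without heterozygous 3 (0.109), the smooth muscle list without heterozygous 1 (0.105), and the circadian, macrophage and adipocyte lists without heterozygous 2 (0.104, 0.0801 and 0.0553). The interferon list was not called between the 2 genotypes (median 0.08, test downward, adjusted p = 0.954), with a mean difference of 0.02 and an SE of 0.65 over mice. Of the 2 pancreas genes, Cela1 rose when adjusted over the list alone (0.43, adjusted p = 0.0116).

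The remaining lists were not called between mutant and heterozygous colons. Medians were 0.01 for the folate list, 0.05 for nucleotide synthesis, 0.01 for methionine, choline and methylation, -0.01 for serine synthesis, -0.10 for the p53 response, 0.14 for DNA repair, -0.06 for Wnt and crypt base genes, 0.02 for mucosal defence and 0.02 for oxidative phosphorylation. The colonocyte, goblet, enteroendocrine, neuron and glia, fibroblast, endothelium and small intestine lists had medians of 0.03, 0.02, -0.07, -0.05, 0.16, -0.04 and -0.07. The B and plasma cell genes had a median of 0.03, the T cell genes -0.15 and Hbb-b2 a log2 fold change of -0.01.

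Across the 13576 probe sets, which are not independent replicates, the log2 fold changes of mutant and heterozygous against wild-type correlated with r = 0.435. Both comparisons use the same 3 wild-type arrays, and unchanged groups simulated against those arrays gave a mean r of 0.462 over 1000 draws. The covariance was 0.0176, and 0.0172 in the simulation.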

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

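The effects of the mutant and heterozygous genotypes against wild-type differed for 3 genes in the test of mutant against heterozygous. Each gene did so on a single probe set, and its other tested probe sets did not pass. The tests on neighbouring genes below were chosen only after the result was seen. The difference in log2 fold change was -2.82 for Trim16, -1.25 for Shmt1, on the probe set that differed most, and -1.16 for Fmo2. In Trim16 and Shmt1 the heterozygous mean lay between the other genotypes. On normalized values returned to the linear scale it covered 40% of the way from wild-type to mutant for Trim16 and 61% for Shmt1. On their other tested probe sets it covered 69% for Trim16 and 55% and 33% for Shmt1, so the order of the genes depended on the probe set. Fmo2 was higher in heterozygous and lower in mutant than in wild-type colons, by log2 fold changes of 0.64 and -0.52 that did not pass by themselves.

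Trim16 lies 36 protein-coding genes from Shmt1 on chromosome 11, and other genes near Shmt1 also stood out. Within 100 genes on each side, Shmt1 left out, 9 of 104 probe sets of 7 genes had an unadjusted p under 0.01 in mutant against wild-type, against 0.439% of 11836 probe sets elsewhere. They are Trim16 and Gid4 with 2 probe sets each, 2210407C18Rik, Galnt10, Tom1l2, B9d1 and Hand1, of which only 1 probe set of Trim16 passed the adjusted test. Of the 5 of these probe sets that were followed under the alternatives, the call changed for 2210407C18Rik, which passed in 7 of 13 and in 2 of 9 fits without an array, and for Gid4, which passed with array weights (adjusted p = 0.0265). Of the 9 probe sets, 5 were lower and 4 higher in mutant colons. Another gene named above, Psmd3, lies on the same chromosome but 638 genes away.

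The tables argue against loss of the Shmt1 product acting on genes wherever they lie as the cause of this cluster: 0 of 112 equally long stretches elsewhere held as large a share, the highest having 3.57%. DNA of the donor strain kept around Shmt1 through backcrossing is a candidate explanation: it needs a raised share near Shmt1, and 8.65% was found. In heterozygous against wild-type, where mice would carry such DNA too, the share was 2.88% against 1.67% elsewhere, but 18 of 112 stretches held as large a share. In mutant against heterozygous it was 6.73%, and 0 of 112 stretches held as large a share, but the highest came close with 6.56%. Whether sequence differences under single probes, without a change in the transcript, account for part of it cannot be told apart here. Only 3 of these genes had further probe sets, of which 2 of 3 changed the same way. The further probe set of Galnt10 did not, with a log2 fold change of 0.20 against -0.65 (unadjusted p = 0.19 in limma's test). An effect of the altered Shmt1 locus itself on nearby genes would raise the share too and was not tested.

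With 3 arrays per genotype there are 10 splits of 6 arrays, too few for a share under 0.05. In mutant against wild-type the real split gave 3 probe sets and the highest other 1, so that 1 of the 10 splits gave as many. In heterozygous against wild-type all 10 splits gave 0. In mutant against heterozygous the real split gave 3 probe sets and the highest other 20, and 2 of 10 splits gave at least 3. The split with 20 set heterozygous 1, mutant 2 and mutant 3 against the others. These 3 mice had the lowest interferon means of all mice, 7.68, 8.27 and 8.05, and the lowest T cell means, 6.34, 7.42 and 6.91. On an Ighm probe set they read 10.6, 15.9 and 2.6, and every other mouse at least 1255. That probe set was chosen after its values were seen. On the leading Ighm probe set they read 255.9, 518 and 431.4 and did not stand apart. All these values come from the same arrays as the split, so they are no separate support for it. The count and these values hint at a structure among the arrays that does not follow genotype. Its source was not tested. For the gene lists, the real counts were 5, 2 and 6, the highest others 6, 8 and 8, and 2, 10 and 3 of the 10 splits gave as many.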

How the results depend on the processing

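No named gene value or list call changed direction under any alternative. Counts were compared by size and not by direction, and there the direction did change. In mutant against heterozygous, 5 probe sets were higher and 2 lower without heterozygous 3, where the main fit had 0 and 3. Without heterozygous 2, 5 lists were up and 0 down, where the main fit had 3 and 3. Removing the 3 arrays numbered 1 and adding the beta-actin 3'/5' ratio were chosen after seeing the data. In mutant against wild-type, where 3 probe sets passed, 9 did with array weights, 9 without the 3 arrays numbered 1, 5 with the beta-actin ratio as a covariate and 35 at an unadjusted p under 0.01 with an absolute log2 fold change of at least 0.58. In heterozygous against wild-type 134 passed with array weights and 81 at that unadjusted threshold. In mutant against heterozygous 5 passed with only the 2 genotypes in the fit and 98 at the unadjusted threshold. Leaving out 1 array gave 2 to 4, 0 to 3 and 1 to 7 probe sets in these comparisons. The labels do not say what the replicate numbers share, and the rule for pairing, every same-numbered pair over 0.1, was not met: deviations of same-numbered arrays correlated with r from -0.059 to 0.46, 5 of 9 pairs over 0.1. This rule cannot exclude a shared set. Deviations were taken from each genotype's mean, so a trend from number 1 to 3 would leave number 2 near 0. The pairs numbered 2 had r of 0.026, 0.012 and -0.059. As a hint from the data, 6 of 9 arrays correlated best with an array of their own number, and the beta-actin ratio fell from number 1 to 3 in every genotype. The cre control read 12578, 11546 and 11929 in the arrays numbered 1 and 8588 to 9740 in the others. With the replicate number as a block 5, 0 and 8 probe sets passed, and 8, 2 and 7 lists. The leading Shmt1 probe set passed in mutant against wild-type with the beta-actin ratio as a covariate (log2 fold change -0.94, adjusted p = 0.0326; the range over the other alternatives was 0.0859 to 1). Leaving out 1 array moved it between -0.96 and -0.78, and in heterozygous against wild-type between -0.43 and -0.14. The 5, 2 and 6 lists shifted became 0, 0 and 0 with an estimated correlation and 0, 0 and 1 with fry, the circadian list, and 3 to 6, 1 to 4 and 1 to 9 when 1 array was left out. The cause of these changes was not tested. The correlation of the 2 genotypes' fold changes lay between 0.197 and 0.578 without 1 array, and the jackknife SE computed from these fits was 0.325. Over the 60 named gene values, 725 of 760 values under other alternatives and 527 of 537 without an array kept direction and side of the threshold. A probe set under a filter gave no value. Most of the named values had not passed in the main fit, so for them keeping the side means failing again, and these counts say little about stability. Of the 13 list calls, 36 of 130 values under other alternatives and 26 of 117 without an array lost the call.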

Other observations

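The tests of explanations in this part were chosen only after the result was seen. Probe sets annotated to Ighm, the immunoglobulin mu chain, did not all move together. On one of them the signal was 2303, 1902 and 1255 in wild-type 1, 2 and 3, 10.6, 2328 and 2831 in heterozygous 1, 2 and 3, and 2865, 15.9 and 2.6 in mutant 1, 2 and 3. On another the signals were 429.1, 127.7 and 586.6 in wild-type, 582, 255.9 and 113.3 in heterozygous and 117.6, 1235 and 900.4 in mutant colons. On the leading probe set, with the highest mean log2 signal, wild-type read 865.6 ± 206 (SD, n = 3), heterozygous 342.3 ± 81.7 and mutant 471.8 ± 43.6. A dimmer probe set went the same way. It read 110.9, 164.5 and 125.7 in wild-type, 58.9, 109.6 and 80.9 in heterozygous and 91.4, 78 and 111.8 in mutant colons. The means of 4 T cell genes, on the log2 scale, were 9.11, 8.5 and 7.91 in wild-type, 6.34, 8.75 and 8.12 in heterozygous and 8.57, 7.42 and 6.91 in mutant colons. The 3 lowest of these, in heterozygous 1, mutant 2 and mutant 3, came from the mice that read 10.6, 15.9 and 2.6 on Ighm. The same mice had the lowest interferon means.

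Interferon genes were lower on average in both mutant and heterozygous colons, and single mice differed widely. The tables argue against a linear trend with the beta-actin 3'/5' ratio as the whole cause: with the 95% interval of its slope within genotypes, the ratio allowed a difference in the interferon mean no lower than -0.15 in mutant and -0.13 in heterozygous colons, where the differences were -0.78 and -0.80. Differences between single animals that do not follow genotype, such as exposure to microbes, may account for it: 2 of the 6 mutant and heterozygous mice, 1 of each, had an interferon mean at or above the lowest wild-type mouse. Fewer macrophages and myeloid cells stay open: their marker mean differed from wild-type by -0.038 (SE 0.18) in heterozygous and by -0.26 (SE 0.17) in mutant colons, too wide a spread to decide. A genotype effect of variable size was not tested.

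Circadian genes were grouped into 2 arms whose means differed in opposite directions between mutant and heterozygous colons, clearly beyond the spread only for the Per arm. These arms were defined after the values were seen. The mean of Arntl, Npas2 and Clock was 8.90 in mutant, 8.64 in wild-type and 8.39 in heterozygous colons on the log2 scale, and that of Per1, Per2, Per3, Dbp, Tef and Hlf 8.69, 9.08 and 9.38, with Clock itself going with the Per arm (-0.32 in mutant against heterozygous). The difference between the arms changed by 1.21 (SE 0.53) from heterozygous to mutant, and no mutant value overlapped a heterozygous one (exact permutation test, two-sided, p = 0.1, the smallest possible). Because the arms were chosen from values already seen, this change does not decide whether the colons were collected at another time of day, and the labels used here give no time of collection. An effect of genotype on the clock was not tested.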
